A study of Mus musculus with 16 samples.

How the data were processed

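Gene expression was measured on 16 Affymetrix mouse arrays with perfect-match probes only, each carrying RNA from a pool of macrophages isolated from adipose tissue of mice aged 19 to 21 weeks. Per the labels, fat was digested with collagenase and cells were taken with CD11b beads, while another label names F4/80-positive cells; RNA from 300000 cells went through 24 cycles of cDNA amplification. The knockout carries floxed Sucnr1 alleles and Cre recombinase under the lysozyme M promoter, which acts in myeloid cells, and the control, called wild type here, carries the floxed alleles alone. SAT is subcutaneous and VAT visceral fat. The labels also hold the letters NCD, which they do not spell out, and no use was made of them here.

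The deposited values are log2 probe set summaries that the authors made by RMA with the affy package, per the processing notes, which give no versions; RMA corrects for background and normalises arrays to common quantiles at the probe level. The deposited file holds 45141 probe sets, of which 104 are controls. The probe table at hand lists 29449 of them, 28898 with 1 gene and 551 with several, and leaves 15588 probe sets that are not controls without a gene. Gene identifiers of 28689 probe sets were found in the gene table (mouse assembly GRCm38.p6, used for names only), which changed 0 symbols. Each of 17097 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for 7180 genes with more than 1 probe set. The deposited values were used as given, with no filter on dim probe sets. Array data have no read depth, and the number of arrays limits the precision.

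Groups follow genotype and depot as labelled, with 4 arrays each. The labels give day 1 or day 2, and each day holds 2 pools of every group, so day was a fixed term. Pool numbers were not in the model because the labels do not say that pools of 1 number share animals. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 16 arrays, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. There were 6 comparisons: VAT minus SAT in each genotype, knockout minus wild type in each depot and averaged over the depots, and the knockout effect in VAT minus that in SAT. Errors of log2 changes are the standard errors of the fit.

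The 34 gene lists were written before the data were examined. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists within a comparison; 1 of the list calls, that of the positional list in the knockout depot comparison, held with the estimated correlation. Members that passed were counted over all genes and adjusted over the list alone. The comparisons, models, rules and most alternatives were also set before the data were examined. Genes are named by 1 rule: in each comparison up to 12 with the largest rise and 12 with the largest fall among those that passed with the same sign on both days, without unnamed gene models, or the 10 with the smallest p where fewer than 10 passed; up to 4 members of smallest p in each list described; and Sucnr1 and Lyz2 throughout. Arg1, Retnla, Chil3 and Mrc1 fall outside this rule in the knockout comparisons within a depot, as do values in a single depot given beside an average over both.

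The model was tested on simulated data with known changes before use. In a simulated comparison of knockout and wild type in SAT, 60% of changes of 0.5 on the log2 scale and 86% of changes of 1 were recovered, and 12 of 185 calls were false. Simulated noise was drawn separately for each gene and array, with 200 genes changed and no difference in spread between arrays. These rates therefore do not carry over to the real arrays, whose spread differed between the genotypes.

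The alternatives were no day term, each day alone, pool number as a replicate block in several forms, the arrays of the compared groups alone, a filter that removed probe sets in the lowest 40% by mean, other ways to join probe sets of a gene, arrays centred on their medians, quantile normalization, array weights, an intensity trend with robust settings, a principal component of the residuals as a term, and each array left out in turn. Array spread as a term, and the fit without the 4 arrays of smallest spread, were added after the data had been seen.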

Results

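The data are expression values of 17097 mouse genes in macrophages isolated from fat, in 4 groups of 4 pools each: wild-type subcutaneous fat (WT SAT), wild-type visceral fat (WT VAT), knockout subcutaneous fat (KO SAT) and knockout visceral fat (KO VAT). Each group has 2 pools on each of 2 days. The deposited log2 values ran from 2.91 to 13.19, and the number of arrays limits the precision of every comparison. Correlations between arrays of 1 group were computed across all probe sets, which are not independent replicates. They lay between 0.986 and 0.992 in WT SAT, 0.942 and 0.990 in WT VAT, 0.989 and 0.996 in KO SAT, and 0.988 and 0.995 in KO VAT. The first principal component (PC1) held 57.5% of the variance.

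The spread of values differed between the genotypes. The interquartile range of the values on an array was 2.503 ± 0.109 log2 units (SD, n = 8) on the arrays labelled KO and 2.251 ± 0.186 (SD, n = 8) on those labelled WT, a difference of 0.25 (exact permutation test, two-sided, p = 0.00699). The difference was 0.27 on day 1 and 0.23 on day 2. The values were 2.20 ± 0.08 in WT SAT, 2.30 ± 0.26 in WT VAT, 2.52 ± 0.12 in KO SAT and 2.49 ± 0.11 in KO VAT (SD, n = 4). WT VAT pools 3 and 4, at 2.504 and 2.536, lay within the range of the knockout arrays, which ran from 2.36 to 2.63.

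**Figure D1:**
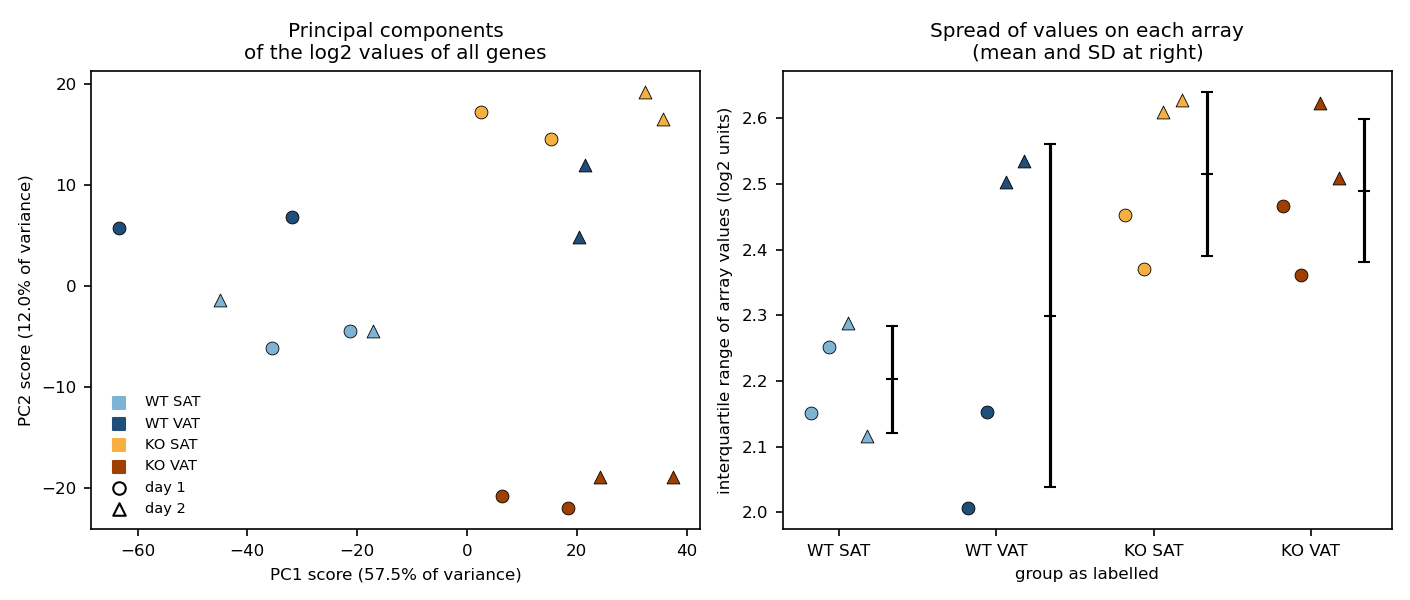
The left panel places each of the 16 arrays by its scores on PC1 (57.5% of variance) and PC2, with circles for day 1 and triangles for day 2, and colours for the 4 groups as labelled. The right panel gives the interquartile range of the log2 values on each array with the mean and SD of its group; the knockout arrays lie between 2.36 and 2.63 and the wild-type arrays between 2.01 and 2.54.

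Sucnr1, the receptor for extracellular succinate and the gene deleted in the knockout, had 1 probe set. Its log2 value was 3.54 ± 0.03 in WT SAT, 3.52 ± 0.12 in WT VAT, 3.55 ± 0.09 in KO SAT and 3.53 ± 0.08 in KO VAT (SD, n = 4), at percentile 5.58 of all probe sets. The median of 41 olfactory receptor genes, typical of the olfactory epithelium, was 4.06 and their 95th percentile 4.78, so the Sucnr1 probe set was not above background and does not check the genotype labels. Of 135 named genes, Sucnr1, Chil3 and Pdcd1lg2 had means under this 95th percentile in all 4 groups. A further 19 had means under it in 1 to 3 groups, and their log2 changes against those groups are not exact sizes: Blk, Ceacam10, Dsp, H2-DMb1, Hoxc8, Icos, Idi1, Igkj1, Krt14, Pate4, Prg4, Prkg2, S100a4, Sdhd, Svs2, Svs3a, Svs4, Svs6 and Tek. The log2 change, knockout minus wild type, was 0.0043 in SAT, -0.042 on day 2 alone, and 0.01 in VAT, -0.02 on day 1 alone; neither passed. Lyz2, the lysozyme gene whose promoter drives Cre in this knockout, was at 11.12 ± 0.21 in WT SAT, 10.57 ± 0.15 in WT VAT, 10.48 ± 0.32 in KO SAT and 9.99 ± 0.33 in KO VAT (SD, n = 4). Lyz2 fell by 0.64 in KO SAT against WT SAT (adjusted p = 0.00525) and by 0.58 in KO VAT against WT VAT (adjusted p = 0.0156), but the latter did not pass without WT VAT pool 2, KO VAT pool 1 or KO VAT pool 2 (-0.48, -0.53 and -0.53). Only the knockout carries Cre, so these falls cannot be told apart from an effect of Cre. VAT minus SAT, Lyz2 was at -0.55 in wild type (adjusted p = 0.0516) and -0.49 in knockout (adjusted p = 0.072), and the knockout effects on it differed by 0.06 (-0.21 on day 1 alone; adjusted p = 0.958), none of which passed. The other Sucnr1 changes did not pass: -0.03 and -0.02 for VAT minus SAT in wild type and knockout, 0.01 for the knockout effect over both depots and 0.01 for the difference of the knockout effects.

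The first depot comparison, VAT minus SAT on the wild-type arrays, asks how macrophages of the depots differ when Sucnr1 is intact. Slc7a2, a transporter of cationic amino acids, rose 6.49-fold (log2 change 2.70 ± 0.17, SE, n = 4 pools per group, adjusted p = 3.24e-07), and the chemokine Cxcl12 rose by 2.77 ± 0.23 (adjusted p = 5.36e-06). The chemokine Ccl8 fell by 2.94 ± 0.20 (adjusted p = 7.05e-07). Fcna, Folr2 and F13a1, expressed by tissue-resident macrophages, fell by 2.32, 1.73 and 1.55. Of the genes with the largest falls in WT VAT, 3 are skeletal muscle genes, which no list covers: the troponin gene Tnnc2 fell by 4.17 ± 0.30 (17.9-fold, adjusted p = 9.28e-07), the actin gene Acta1 by 3.91 and the calcium pump gene Atp2a1 by 3.87. The steroid-metabolising enzyme gene Akr1c18 fell by 3.79 ± 0.15 (adjusted p = 1.83e-09), the retinol dehydrogenase gene Adh7 by 2.49 and the homeobox gene Emx2 by 1.33.

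Among macrophage lists on the wild-type arrays, 6 of 26 resident macrophage genes fell and 0 rose (11 fell adjusted over the list alone). The resident macrophage median was -0.44 (adjusted p = 8.76e-13, and adjusted p = 0.188 with an estimated correlation). Of 24 lipid-associated macrophage genes, 4 fell and 1 rose (11 and 1 adjusted over the list alone); Gpnmb fell by 0.84 and the protease gene Ctsl by 0.56, while the lipid-binding Fabp4 rose by 0.91, and did not pass without WT SAT pool 1 (0.86) or WT VAT pool 2 (0.75). The lipid-associated median was -0.28 (adjusted p = 3.77e-06, and adjusted p = 0.453 with an estimated correlation). Of 29 alternative activation genes, 3 fell and 2 rose (9 and 3 adjusted over the list alone). The alternative activation median was -0.13 (adjusted p = 0.0448, and adjusted p = 0.51 with an estimated correlation). Retnla, induced by interleukin-4, fell by 0.73, and Tgm2 rose by 0.58 and Egr2 by 0.68, which did not pass without WT VAT pool 3 (0.52 and 0.65). Interferon response genes rose as a list (2 of 21 up, 6 adjusted over the list alone). The interferon median was 0.25 (adjusted p = 9.11e-07, and adjusted p = 0.453 with an estimated correlation). Classical activation genes moved up, 5 of 34 with 1 fallen (7 and 4 adjusted over the list alone). The classical activation median was 0.08 (adjusted p = 0.0306, and adjusted p = 0.463 with an estimated correlation). Cxcl10 rose by 1.77 and Ccl5 by 1.44, both chemokines for T cells, whereas the acute-phase gene Saa3 fell by 2.26. Unfolded protein response genes rose (6 of 20, 8 up and 1 down adjusted over the list alone), among them Trib3 by 1.24 and Atf5 by 0.88. The unfolded protein median was 0.23, and 0.15 after quantile normalization (adjusted p = 2.86e-06, and adjusted p = 0.453 with an estimated correlation).

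Markers of other cells also differed between the wild-type depots. Stromal progenitor markers rose (8 of 20, 11 adjusted over the list alone), with the matrix genes Mfap5 at 1.82, Fstl1 at 0.99 and Postn at 0.68. The stromal median was 0.58 (adjusted p = 8.76e-13, and adjusted p = 0.188 with an estimated correlation). T cell markers fell (6 of 17, 6 down and 1 up adjusted over the list alone), with Cd3e at -1.73 and Icos at -1.80. The T cell median was -0.19 (adjusted p = 3.77e-06, and adjusted p = 0.188 with an estimated correlation). B cell markers fell (3 of 16, 5 adjusted over the list alone), with Blk at -0.91. The B cell median was -0.31 (adjusted p = 3.77e-06, and adjusted p = 0.204 with an estimated correlation). Erythroid markers fell (2 of 7, 2 adjusted over the list alone), with the globin gene Hbb-b2 at -2.41. The erythroid median was -0.27 (adjusted p = 0.0115, and adjusted p = 0.453 with an estimated correlation). Peritoneal macrophage genes fell as a list, with 3 of 19 fallen and 2 risen (5 and 2 adjusted over the list alone). The peritoneal median was -0.15 (adjusted p = 0.0319, and adjusted p = 0.188 with an estimated correlation). Mast cell and basophil markers were directed down as a list, though no member passed over all genes (0 of 13, 2 down and 1 up adjusted over the list alone, median -0.13, adjusted p = 0.0448, and adjusted p = 0.51 with an estimated correlation). So were mammary epithelial markers (0 of 16, 1 down adjusted over the list alone, median -0.11, adjusted p = 0.0448, and adjusted p = 0.498 with an estimated correlation). The cell cycle list was directed down too, with no member that passed (0 of 24, 0 adjusted over the list alone, median -0.12, adjusted p = 0.0448, and adjusted p = 0.453 with an estimated correlation). Endothelial markers were directed up as a list, with no member that passed over all genes (0 of 20, 1 up adjusted over the list alone, median 0.15, adjusted p = 0.000253, and adjusted p = 0.453 with an estimated correlation). Cyclic AMP response genes rose (2 of 16, 2 adjusted over the list alone, median 0.18, adjusted p = 0.0448, and adjusted p = 0.453 with an estimated correlation).

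In the wild-type depot comparison, 486 genes passed in limma, 260 higher and 226 lower in WT VAT, with 129 changed at least 2-fold. On day 1 alone 199 genes passed and on day 2 alone 4222, and 60 when the knockout arrays were left out. With array spread as a term 1502 passed (507 higher and 995 lower), and 231 to 1711 with 1 array left out. Other splits of the 8 wild-type arrays gave more genes, up to 3998, so the count is no larger than arbitrary splits can give. Of the 16 lists that passed, 9 kept the call with array spread as a term. The 7 that lost it were classical activation, peritoneal macrophages, mast cells and basophils, mammary epithelium, erythroid cells, the cell cycle and cyclic AMP response. Medians that moved by over 1.5 times with that term were 0.16 for interferon response, -0.028 for mast cells and basophils, 0.30 for endothelium, -0.067 for mammary epithelium, -0.13 for erythroid cells, -0.010 for the cell cycle, 0.056 for the unfolded protein response and 0.089 for cyclic AMP response.

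The same depot comparison on the knockout arrays, KO VAT minus KO SAT as labelled, asks how the depots differ without Sucnr1 in myeloid cells. Genes of seminal vesicle secretions were among those that fell furthest: the log2 change of Svs4 was -7.68 ± 0.52 (SE, n = 4 pools per group, adjusted p = 3.17e-07), and Svs6, Svs2 and Svs3a fell by 6.35, 6.16 and 6.06. None of these 4 genes was above the background level of 4.78 in KO VAT, so the sizes of their falls are not exact. Svs4 was at 11.44 ± 0.32 in KO SAT and at 3.76 ± 0.07 in KO VAT, 3.79 ± 0.06 in WT VAT and 4.76 ± 1.70 in WT SAT (SD, n = 4), where pool 2 stood at 7.30. Akr1c18 rose 30.4-fold (4.93 ± 0.15, adjusted p = 8.31e-12), Adh7 rose by 3.86 and Emx2 by 3.26, 3 genes that fell from SAT to VAT on the wild-type arrays. Ccl8 rose by 2.12, and Tnfrsf11b, a decoy receptor that limits bone resorption, fell by 3.22.

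Interferon response genes fell on the knockout arrays (13 of 21, 19 adjusted over the list alone), with Cmpk2 at -1.02, Mx1 at -0.84 and Rsad2 at -0.51. The interferon median was -0.51 (adjusted p = 4.83e-20, and adjusted p = 0.147 with an estimated correlation). Classical activation genes fell, 11 of 34 with 1 risen (15 and 2 adjusted over the list alone). The classical activation median was -0.26 (adjusted p = 5.24e-09, and adjusted p = 0.0882 with an estimated correlation). Ccl5 fell by 1.77, Cxcl10 by 1.34, the costimulatory Cd86 by 1.04 and the transcription factor gene Irf1 by 0.67. MHC class II genes, which present antigen, fell (5 of 12, 7 adjusted over the list alone), with H2-Eb1 at -1.10, Cd74 at -0.90 and H2-Ab1 at -0.67. The MHC class II median was -0.29 (adjusted p = 5.98e-06, and adjusted p = 0.232 with an estimated correlation). Alternative activation genes fell, 5 of 29 with 0 risen (8 adjusted over the list alone), with the eosinophil chemokine Ccl24 at -2.03. The alternative activation median was -0.11 (adjusted p = 0.00424, and adjusted p = 0.367 with an estimated correlation). Lipid-associated genes fell, 6 of 24 with 1 risen (9 and 1 adjusted over the list alone). The lipid-associated median was -0.32 (adjusted p = 1.08e-05, and adjusted p = 0.389 with an estimated correlation). Itgax fell by 1.04 and the fatty acid receptor gene Cd36 by 0.88, while the protease gene Ctsk rose by 0.73. Resident macrophage genes moved down, 5 fallen and 2 risen of 26 (7 and 2 adjusted over the list alone), with Igf1 at -1.06. The resident macrophage median was -0.16 (adjusted p = 0.0157, and adjusted p = 0.623 with an estimated correlation). Genes that mark fat by body position rose, 9 of 20 with 2 fallen (10 and 5 adjusted over the list alone), with Emx2, Sfrp2 at 2.30, Hoxc10 at 1.61 and Thy1 at 0.81. The positional median was 0.27 (adjusted p = 0.00028, and adjusted p = 0.0417 with an estimated correlation).

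Lymphocyte, erythroid and endothelial markers moved with the depot on the knockout arrays as well. T cell markers rose (4 of 17, 4 adjusted over the list alone), with Icos at 1.25, which did not pass without KO SAT pool 3 or 4 or KO VAT pool 1 or 3 (1.04 to 1.19). The T cell median was 0.12 (adjusted p = 0.00126, and adjusted p = 0.267 with an estimated correlation). B cell markers rose (1 of 16, 7 up and 1 down adjusted over the list alone). The B cell median was 0.21 (adjusted p = 0.000377, and adjusted p = 0.267 with an estimated correlation). Endothelial markers fell (2 of 20, 8 adjusted over the list alone). The endothelial median was -0.49 (adjusted p = 1.81e-07, and adjusted p = 0.267 with an estimated correlation). Erythroid markers rose (2 of 7, 3 adjusted over the list alone). The erythroid median was 0.28 (adjusted p = 0.00327, and adjusted p = 0.292 with an estimated correlation). Peritoneal macrophage genes rose, 5 of 19 with 1 fallen (6 and 2 adjusted over the list alone), led by Prg4 at 2.86, Serpinb2 at 2.98, Cxcl13 at 1.74 and Slpi at 1.35. The peritoneal median was 0.08 (adjusted p = 0.00652, and adjusted p = 0.0882 with an estimated correlation). Hypoxia and glycolysis genes rose (2 of 22 with 1 fallen, the same adjusted over the list alone), with Egln3 at 1.63 and Adm at 1.34. The hypoxia median was 0.11 (adjusted p = 0.0157, and adjusted p = 0.623 with an estimated correlation). Mast cell and basophil markers rose (2 of 13, 3 adjusted over the list alone, median 0.09, adjusted p = 0.00479, and adjusted p = 0.388 with an estimated correlation). Cholesterol synthesis genes rose (1 of 17, 3 adjusted over the list alone, median 0.11, adjusted p = 0.0061, and adjusted p = 0.0882 with an estimated correlation). Cell cycle genes rose (2 of 24, 4 adjusted over the list alone, median 0.13, adjusted p = 0.00424, and adjusted p = 0.203 with an estimated correlation). Citric acid cycle genes rose as a list (1 of 21 risen and 1 fallen, the same adjusted over the list alone, median 0.10, adjusted p = 0.0465, and adjusted p = 0.623 with an estimated correlation). The ribosomal protein list was directed up, with no member that passed (0 of 29, 0 adjusted over the list alone, median 0.07, adjusted p = 0.0061, and adjusted p = 0.657 with an estimated correlation). Iron handling genes fell (2 of 18, 6 adjusted over the list alone, median -0.12, adjusted p = 0.00327, and adjusted p = 0.367 with an estimated correlation).

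In the knockout depot comparison, 738 genes passed, 329 higher and 409 lower in KO VAT, with 158 changed at least 2-fold. On day 1 alone 262 genes passed and on day 2 alone 199, against 2047 when the wild-type arrays were left out. With array spread as a term 1968 passed (1067 higher and 901 lower), and 461 to 1054 with 1 array left out. All 19 lists that passed kept the call with array spread as a term. Across 123 genes that passed in both genotypes, 100 differed between depots in opposite directions (Spearman correlation across genes -0.83, over all 17097 genes 0.0085).

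**Figure D2:**
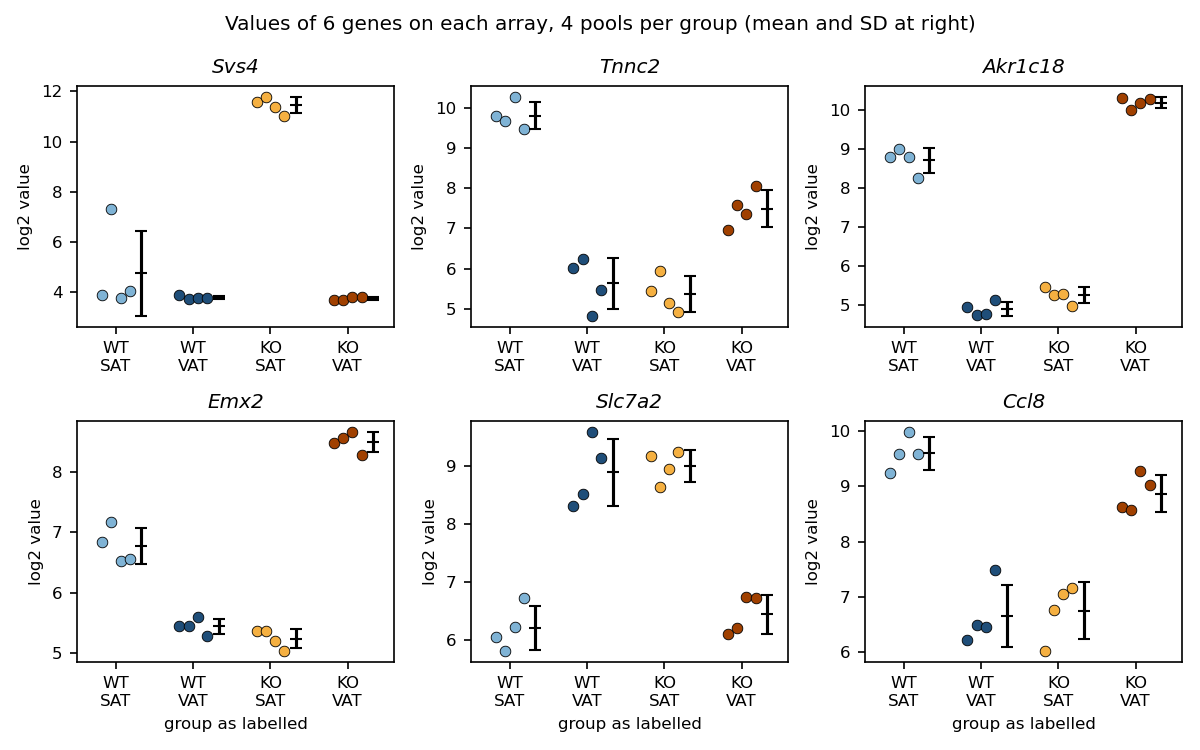
Log2 values of Svs4, Tnnc2, Akr1c18, Emx2, Slc7a2 and Ccl8 on each array, 4 pools per group as labelled, with the mean and SD of each group. Akr1c18 stood at 8.70 in WT SAT, 4.91 in WT VAT, 5.26 in KO SAT and 10.18 in KO VAT, and Svs4 at 11.44 in KO SAT and between 3.76 and 4.76 on average in the other groups.

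The comparison of KO SAT with WT SAT, as labelled, asks what the knockout, Cre included, changes in macrophages of subcutaneous fat. Under an exchange of depot labels in 1 genotype, left open below, it would also set SAT against VAT. The chemokines Cxcl10 and Ccl5 rose by 2.06 ± 0.14 and 1.97 ± 0.17 (SE, n = 4 pools per group, adjusted p = 2.21e-07 and 5.9e-06). The cytokine Il6 rose 7.06-fold (2.82 ± 0.30, adjusted p = 4.39e-05) and Cxcl12 rose by 3.01. Ccl8 fell by 2.85, Fcna by 2.61, Folr2 by 1.21 and F13a1 by 1.08. The log2 change of Svs4 was 6.68 ± 0.52 (adjusted p = 1.42e-06), and 7.51 without WT SAT pool 2, and that of Svs2 was 5.99; neither was above the background level of 4.78 on average in WT SAT, so these sizes are not exact. The muscle genes Tnnc2 and Acta1 fell by 4.44 and 4.10, Adh7 fell by 3.65, Akr1c18 fell by 3.45, and the Y-linked multicopy gene Ssty2 fell by 3.74 ± 0.71 (adjusted p = 0.0024).

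Interferon response genes rose in KO SAT, 16 of 21 with 0 fallen (18 adjusted over the list alone), with the RNA sensor gene Ifih1 at 1.07, Ifit1 at 1.00 and Parp14 at 0.83. The interferon median was 0.57, and 0.36 after quantile normalization (adjusted p = 1.94e-09, and adjusted p = 0.473 with an estimated correlation). Classical activation genes rose, 16 of 34 with 3 fallen (16 and 4 adjusted over the list alone). The classical activation median was 0.34, and 0.19 after quantile normalization (adjusted p = 6.77e-05, and adjusted p = 0.473 with an estimated correlation). Alternative activation genes did not move as a list: 6 of 29 rose and 3 fell, also adjusted over the list alone, with a median of -0.03, a mean of 0.09 and a test directed up (adjusted p = 0.601). In that list Egr2, a transcription factor gene induced by interleukin-4, rose by 1.26, Ccl24 by 1.71, Klf4 by 0.75 and Tgm2 by 0.60. Arg1, Retnla, Chil3 and Mrc1, common markers of alternative activation, were chosen after their values were seen. Arg1 fell by 0.64 (adjusted p = 0.0386), but did not pass without WT SAT pool 2, 3 or 4 or any 1 of the 4 KO SAT pools (-0.69 to -0.49). Chil3, at 4.47 in WT SAT and 3.64 in KO SAT, was not above the background level of 4.78 in either group, so no change in its expression is given. The changes of Retnla (0.04, and -0.30 after quantile normalization; adjusted p = 0.848) and Mrc1 (-0.17, and 0.07 on day 2; adjusted p = 0.535) did not pass. Resident macrophage genes fell, 9 of 26 with 1 risen (9 and 1 adjusted over the list alone). The resident macrophage median was -0.19, -0.10 with each array centred on its median and -0.36 after quantile normalization (adjusted p = 0.014, and adjusted p = 0.561 with an estimated correlation).

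T cell markers fell in KO SAT, 12 of 17 with 1 risen (12 and 1 adjusted over the list alone). The T cell median was -0.36 (adjusted p = 0.000101, and adjusted p = 0.473 with an estimated correlation). B cell markers fell, 10 of 16 with 0 risen (10 down and 1 up adjusted over the list alone). The B cell median was -0.45 (adjusted p = 0.00187, and adjusted p = 0.473 with an estimated correlation). Cd3e fell by 2.00, Icos by 2.23, Cd79a by 1.44 and Cd79b by 1.29. Mast cell and basophil markers fell, 8 of 13 with 1 risen (11 and 1 adjusted over the list alone). The mast cell median was -0.35 (adjusted p = 0.00538, and adjusted p = 0.526 with an estimated correlation). Endothelial markers rose (9 of 20, 14 up and 1 down adjusted over the list alone), with the cadherin gene Cdh5 at 2.21 and the angiopoietin receptor gene Tek at 1.64. The endothelial median was 0.64, and 0.42 after quantile normalization (adjusted p = 0.000101, and adjusted p = 0.526 with an estimated correlation). Stromal markers rose, 11 of 20 with 2 fallen (12 and 3 adjusted over the list alone), with Mfap5 at 1.92 and Fstl1 at 1.15. The stromal median was 0.57 (adjusted p = 0.000182, and adjusted p = 0.473 with an estimated correlation).

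Metabolic and stress lists rose in KO SAT, where array spread was also larger. Fatty acid oxidation rose, 8 of 19 with 2 fallen (10 and 3 adjusted over the list alone), with Hadh at 1.41 and Acadm at 0.86. The fatty acid oxidation median was 0.33, and 0.067 after quantile normalization (adjusted p = 0.00423, and adjusted p = 0.534 with an estimated correlation). The citric acid cycle rose (7 of 21, 7 adjusted over the list alone), with Mdh1 at 0.72 and the succinate dehydrogenase gene Sdhd at 0.50. The citric acid cycle median was 0.27, and 0.070 after quantile normalization (adjusted p = 0.00722, and adjusted p = 0.538 with an estimated correlation). The unfolded protein response rose (8 of 20, 10 adjusted over the list alone), with the chaperone genes Hspa5 at 1.07 and Calr at 0.90. The unfolded protein median was 0.42, and 0.12 after quantile normalization (adjusted p = 0.000513, and adjusted p = 0.534 with an estimated correlation). Oxidative phosphorylation rose (3 of 28, 0 adjusted over the list alone). The oxidative phosphorylation median was 0.15, 0.23 with each array centred on its median and -0.11 after quantile normalization (adjusted p = 0.0257, and adjusted p = 0.695 with an estimated correlation). With array spread as a term these 4 lists turned downward (adjusted p = 0.649, 0.0522, 0.263 and 3.56e-07 in the order given). The early stress response rose, 7 of 24 with 1 fallen (7 and 1 adjusted over the list alone), with Cxcl2 at 0.75 and Hspa1b at 0.84. The early stress median was 0.30, and 0.086 after quantile normalization (adjusted p = 0.000167, and adjusted p = 0.534 with an estimated correlation). Cyclic AMP response genes rose (5 of 16, 5 adjusted over the list alone). The cyclic AMP median was 0.22, and 0.047 after quantile normalization (adjusted p = 0.00722, and adjusted p = 0.473 with an estimated correlation). Cell cycle genes fell (7 of 24, 7 adjusted over the list alone). The cell cycle median was -0.18, -0.090 with each array centred on its median and -0.11 after quantile normalization (adjusted p = 0.0399, and adjusted p = 0.473 with an estimated correlation).

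Between KO SAT and WT SAT 6279 genes passed, 2859 higher and 3420 lower, with 495 changed at least 2-fold; 45.5% of those that passed were higher, 61.6% with each array centred on its median and 20.6% with array spread as a term (270 higher and 1038 lower). Of the 6279, 78.2% kept their sign with array spread as a term. On day 1 alone 582 genes passed, on day 2 alone 6498 and with array spread as a term 1308. With 1 array left out 3071 to 7960 passed. Of the 15 lists that passed, 6 kept the call with array spread as a term and 4 turned downward. The 5 that lost the call were mast cells and basophils (median -0.038), B cells (-0.16), the cell cycle (0.020, with its sign turned), the early stress response (0.0076) and cyclic AMP response (0.15). Other medians with that term were 0.095 for interferon response, 0.18 for classical activation, -0.41 for resident macrophages, -0.24 for T cells and 0.20 for stromal markers. For the lists that turned they were -0.14 for fatty acid oxidation, -0.15 for the citric acid cycle, -0.14 for the unfolded protein response and -0.25 for oxidative phosphorylation.

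The comparison of KO VAT with WT VAT asks the same of visceral fat, with the same limits. Akr1c18 rose 38.7-fold (5.27 ± 0.15, SE, n = 4 pools per group, adjusted p = 1.55e-11), the matrix gene Thbs2 by 3.77, the desmosome gene Dsp by 3.67, Emx2 by 3.05 and Ccl8 by 2.21. Ptgs2, which makes prostaglandin precursors, rose by 2.28 ± 0.38 (adjusted p = 0.00164) and Jun by 1.34. Tnfrsf11b fell by 2.51, Slc7a2 by 2.45 and Ltbp4 by 1.81. Cxcl10 and Ccl5 fell by 1.05 and 1.24 (adjusted p = 0.000294 and 0.000434), where they had risen in SAT. Under exchanged depot labels neither would fall. KO VAT, WT SAT, KO SAT and WT VAT stood at 8.76, 8.04, 10.1 and 9.81 for Cxcl10. Ccl5 stood at 7.13, 6.94, 8.90 and 8.37.

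MHC class II genes fell in KO VAT (4 of 12, 6 adjusted over the list alone), with H2-Eb1 at -0.89 and Cd74 at -0.69. The MHC class II median was -0.28, and -0.42 after quantile normalization (adjusted p = 0.00224, and adjusted p = 0.92 with an estimated correlation). Interferon response genes fell (3 of 21, 1 adjusted over the list alone), with Cmpk2 at -0.74. The interferon median was -0.23, and -0.42 after quantile normalization (adjusted p = 0.0442, and adjusted p = 0.92 with an estimated correlation). Alternative activation genes did not move as a list, 3 of 29 risen and 1 fallen, also adjusted over the list alone (median -0.02, mean 0.02, test directed up, adjusted p = 0.767): Ppard rose by 0.78 and Klf4 by 0.58, and Tgm2 fell by 0.45. Arg1, Retnla, Chil3 and Mrc1, chosen after their values were seen, did not pass, at 0.09, 0.22, -0.05 and 0.66 (adjusted p = 0.795, 0.264, 0.877 and 0.0532), and Chil3 was not above background in either group. After quantile normalization Arg1, Retnla and Chil3 had the opposite sign, at -0.18, -0.02 and 0.01. Peritoneal macrophage genes rose, 6 of 19 with 1 fallen (7 and 1 adjusted over the list alone), with Serpinb2 at 3.68, Prg4 at 2.74, Slpi at 1.55 and Cxcl13 at 1.45. The peritoneal median was 0.12, 0.19 with each array centred on its median and -0.04 after quantile normalization (adjusted p = 0.0419, and adjusted p = 0.234 with an estimated correlation). Positional genes rose, 8 of 20 with 2 fallen (9 and 3 adjusted over the list alone), with Sfrp2 at 2.42. The positional median was 0.09, and 0.16 both with each array centred on its median and after quantile normalization (adjusted p = 0.0419, and adjusted p = 0.234 with an estimated correlation).

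Metabolic lists rose in KO VAT, again where array spread was larger on the arrays labelled KO. The citric acid cycle rose (6 of 21, 9 up and 1 down adjusted over the list alone), with Suclg2, a subunit of the enzyme that makes succinate, at 0.77. The citric acid cycle median was 0.32 (adjusted p = 0.000542, and adjusted p = 0.92 with an estimated correlation). Fatty acid oxidation rose (5 of 19, 12 up and 1 down adjusted over the list alone), with Eci2 at 0.77 and Acadl at 0.64. The fatty acid oxidation median was 0.37, and 0.16 after quantile normalization (adjusted p = 0.0187, and adjusted p = 0.92 with an estimated correlation). Oxidative phosphorylation rose (4 of 28, 3 adjusted over the list alone), with Uqcrfs1 at 0.73 and Ndufs1 at 0.41. The oxidative phosphorylation median was 0.19 but -0.010 after quantile normalization (adjusted p = 0.00102, and adjusted p = 0.92 with an estimated correlation). Hypoxia and glycolysis genes rose, 4 of 22 with 1 fallen (4 and 1 adjusted over the list alone), with Egln3 at 1.86, Adm at 1.15 and Hif1a, the oxygen-regulated transcription factor gene, at 1.04. The hypoxia median was 0.12, 0.19 with each array centred on its median and -0.05 after quantile normalization (adjusted p = 0.0387, and adjusted p = 0.92 with an estimated correlation). With array spread as a term, oxidative phosphorylation (adjusted p = 0.414) and the hypoxia list (adjusted p = 0.892) turned downward. The early stress response rose, 7 of 24 with 2 fallen (10 and 3 adjusted over the list alone), with Nfkbiz at 1.54. The early stress median was 0.30, and 0.10 after quantile normalization (adjusted p = 0.0187, and adjusted p = 0.92 with an estimated correlation). Cholesterol synthesis rose (5 of 17, 7 adjusted over the list alone), with Idi1 at 2.83, Cyp51 at 0.73 and Insig1 at 0.71. The cholesterol median was 0.08, 0.15 with each array centred on its median and 0.14 after quantile normalization (adjusted p = 0.0411, and adjusted p = 0.234 with an estimated correlation).

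Between KO VAT and WT VAT 2724 genes passed, 1740 higher and 984 lower, with 275 changed at least 2-fold; 63.9% of those that passed were higher, 77.1% with each array centred on its median, 51.3% after quantile normalization and 42.2% with array spread as a term (781 higher and 1068 lower). On day 1 alone 5376 genes passed, on day 2 331, in these groups alone 1238 and with 1 array left out 1115 to 4007. Across all genes the knockout effects in VAT and SAT had a Spearman correlation of 0.65. Of genes passing in both, 971 rose, 473 fell and 77 and 99 were opposite. Array spread may give this, as slopes on it correlated with the effects in VAT and SAT (0.63 and 0.72). Of the 10 lists that passed, 5 kept the call with array spread as a term and 2 turned downward. The 3 that lost the call were the citric acid cycle (median 0.076), fatty acid oxidation (0.069) and the early stress response (0.091). Other medians that moved by over 1.5 times with that term were -0.45 for interferon response, -0.18 for MHC class II, 0.051 for peritoneal macrophages, 0.14 for positional genes, -0.11 for hypoxia and glycolysis and -0.051 for oxidative phosphorylation.

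The knockout effect averaged over both depots (knockout minus wild type, n = 8 arrays per genotype) weights SAT and VAT equally, and such an average can come from 1 depot alone. Scd1, which desaturates fatty acids, rose by 1.78 ± 0.20 (SE, adjusted p = 6.94e-05), with 1.32 in SAT and 2.25 in VAT. Nfkbiz, a regulator of NF-kB target genes, rose by 1.46 ± 0.19 (adjusted p = 0.000143), with 1.38 in SAT and 1.54 in VAT. Lyz2 fell by 0.61 ± 0.10 (adjusted p = 0.000573). The average of Il6, 1.33 ± 0.21 (adjusted p = 0.000512), joined 2.82 in SAT with -0.15 in VAT (0.42 on day 1 alone). That of Fcna, -1.12, joined -2.61 in SAT with 0.38 in VAT. Under exchanged labels Il6 would rise both times (KO VAT 7.06, WT SAT 5.55, KO SAT 8.37, WT VAT 7.21). Hif1a rose by 1.04 in VAT and by 0.42 in SAT, where it did not pass without 7 of the 16 arrays, each left out in turn. Its target Egln3 rose by 1.86 in VAT and stood at -0.18 in SAT. The VAT values of Il6 and Fcna and the SAT value of Egln3 did not pass. Among the largest falls were those of the multicopy Y-linked genes Ssty2 (8.11-fold lower, -3.02 ± 0.50, adjusted p = 0.000616), Ssty1 (-2.38) and Orly (-2.05), of Astx6 (-2.81), and of the vomeronasal receptor genes Vmn1r148 (-2.41) and Vmn2r42 (-1.56). Ssty2 stood at 9.31 ± 0.45 in WT SAT, 8.42 ± 1.49 in WT VAT, 5.56 ± 1.42 in KO SAT and 6.13 ± 1.01 in KO VAT (SD, n = 4).

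Averaged over depots, the early stress response rose, 17 of 24 with 1 fallen (17 and 1 adjusted over the list alone), with Egr2 at 0.80, Jun at 0.72, Egr1 at 0.57 and Btg2 at 0.51. The early stress median was 0.36, and 0.17 after quantile normalization (adjusted p = 0.00123, and adjusted p = 0.64 with an estimated correlation). Fatty acid oxidation rose, 11 of 19 with 3 fallen (12 and 3 adjusted over the list alone), with Hadh at 1.10, Acadm at 0.76 and Etfdh at 0.57. The fatty acid oxidation median was 0.32, and 0.13 after quantile normalization (adjusted p = 0.00462, and adjusted p = 0.64 with an estimated correlation). The citric acid cycle rose, 11 of 21 with 1 fallen (11 and 1 adjusted over the list alone), with Mdh1 at 0.65, Suclg2 at 0.58, Sdhd at 0.44 and Mdh2 at 0.28. The citric acid cycle median was 0.28, and 0.12 after quantile normalization (adjusted p = 0.00123, and adjusted p = 0.64 with an estimated correlation). Oxidative phosphorylation rose (9 of 28, 9 adjusted over the list alone), with Uqcrfs1 at 0.58 and Cox5a at 0.32. The oxidative phosphorylation median was 0.16 but -0.07 after quantile normalization (adjusted p = 0.00329, and adjusted p = 0.64 with an estimated correlation). The unfolded protein response rose (8 of 20, 8 adjusted over the list alone), with Hspa5 at 0.87, Xbp1 at 0.70 and Calr at 0.53. The unfolded protein median was 0.24, and 0.011 after quantile normalization (adjusted p = 0.0125, and adjusted p = 0.64 with an estimated correlation). In VAT alone that list did not pass (median 0.07, adjusted p = 0.41). Interferon response genes rose (8 of 21, 7 adjusted over the list alone), with Ifih1 at 0.70 and Ifit1 at 0.46. The interferon median was 0.18 but -0.0012 after quantile normalization (adjusted p = 0.00462, and adjusted p = 0.64 with an estimated correlation). It joined a rise in SAT (median 0.57, 16 risen and 0 fallen) with a fall in VAT (median -0.23, 0 risen and 3 fallen). With depot labels exchanged this is untested: KO VAT exceeded WT SAT for Ifit1 (9.53, 9.17) but not Cmpk2 (8.30, 8.66). Classical activation genes rose, 12 of 34 with 4 fallen (12 and 4 adjusted over the list alone), with Cxcl1 at 0.78 and Cxcl2 at 0.55. The classical activation median was 0.09, 0.17 with each array centred on its median and -0.0070 after quantile normalization (adjusted p = 0.0257, and adjusted p = 0.64 with an estimated correlation). It joined 0.34 in SAT with -0.13 in VAT, where the list did not pass (adjusted p = 0.543). With array spread as a term the citric acid cycle (adjusted p = 0.565), oxidative phosphorylation (0.000205), unfolded protein (0.0128) and interferon (0.112) lists turned downward.

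Stromal markers rose over both depots, 10 of 20 with 2 fallen (11 and 2 adjusted over the list alone), with Dpt at 1.01 and Postn at 0.48. The stromal median was 0.33, and 0.14 after quantile normalization (adjusted p = 0.00462, and adjusted p = 0.64 with an estimated correlation). In VAT alone the stromal list did not pass (median 0.01, 1 risen, adjusted p = 0.448). T cell markers fell, 10 of 17 with 1 risen (13 and 1 adjusted over the list alone), with Cd3g at -0.78, Cd3d at -0.63 and Lat at -0.56. The T cell median was -0.28 (adjusted p = 0.00652, and adjusted p = 0.64 with an estimated correlation). It came from SAT, at -0.36 with 12 fallen; in VAT 0 fell and 1 rose, with a median of -0.03 and a test directed up (adjusted p = 0.845). MHC class II genes fell (5 of 12, 5 adjusted over the list alone), with H2-DMb2 at -0.72, H2-Ob at -0.61 and H2-DMb1 at -0.36. The MHC class II median was -0.22, and -0.14 with each array centred on its median (adjusted p = 0.0416, and adjusted p = 0.64 with an estimated correlation). In SAT alone MHC class II genes did not pass as a list (median -0.02, 4 risen and 5 fallen, adjusted p = 0.685). Alternative activation genes did not move as a list: 5 of 29 rose and 6 fell (4 and 4 adjusted over the list alone), with Egr2 at 0.80, Klf4 at 0.67 and Clec7a at 0.60. The alternative activation median was 0.0034 (adjusted p = 0.599). Lipid-associated macrophage genes did not move as a list (3 of 24 risen and 3 fallen, 3 and 2 adjusted over the list alone), with Fabp4 at 0.63, Abcg1 at 0.57 and Gpnmb at -0.47. Among the 50 genes named over both depots, 9 had effects of opposite sign in SAT and VAT: Svs4, Il6, Ifit1, Cd3d, Cd3g, H2-Ob, Fcna, Fabp4 and Egln3.

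Over both depots 8831 genes passed, 3841 higher and 4990 lower, with 197 changed at least 2-fold; 43.5% of those that passed were higher, 60.5% with each array centred on its median and 24.8% with array spread as a term (335 higher and 1018 lower). Of the 8831, 1444 passed with 1 sign in both depots, 4080 in SAT alone, 944 in VAT alone, 2318 in neither and 45 in both with opposite signs. In all, 366 had opposite signs in the depots. The sign of the averaged effect was kept by 71.7% of the 8831 with array spread as a term. On day 1 alone 6193 genes passed and on day 2 alone 4279, against 1353 with array spread as a term and 4670 without the 4 arrays of smallest spread. None of the 10 list calls over both depots held with array spread as a term: 6 were lost and 4 turned downward. Medians with that term were 0.046 for the early stress response, -0.076 for fatty acid oxidation, -0.041 for the citric acid cycle, -0.18 for oxidative phosphorylation, -0.19 for the unfolded protein response and -0.084 for interferon response. They were 0.031 for classical activation, 0.040 for stromal, -0.085 for T cell and -0.14 for MHC class II genes.

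**Figure D3:**
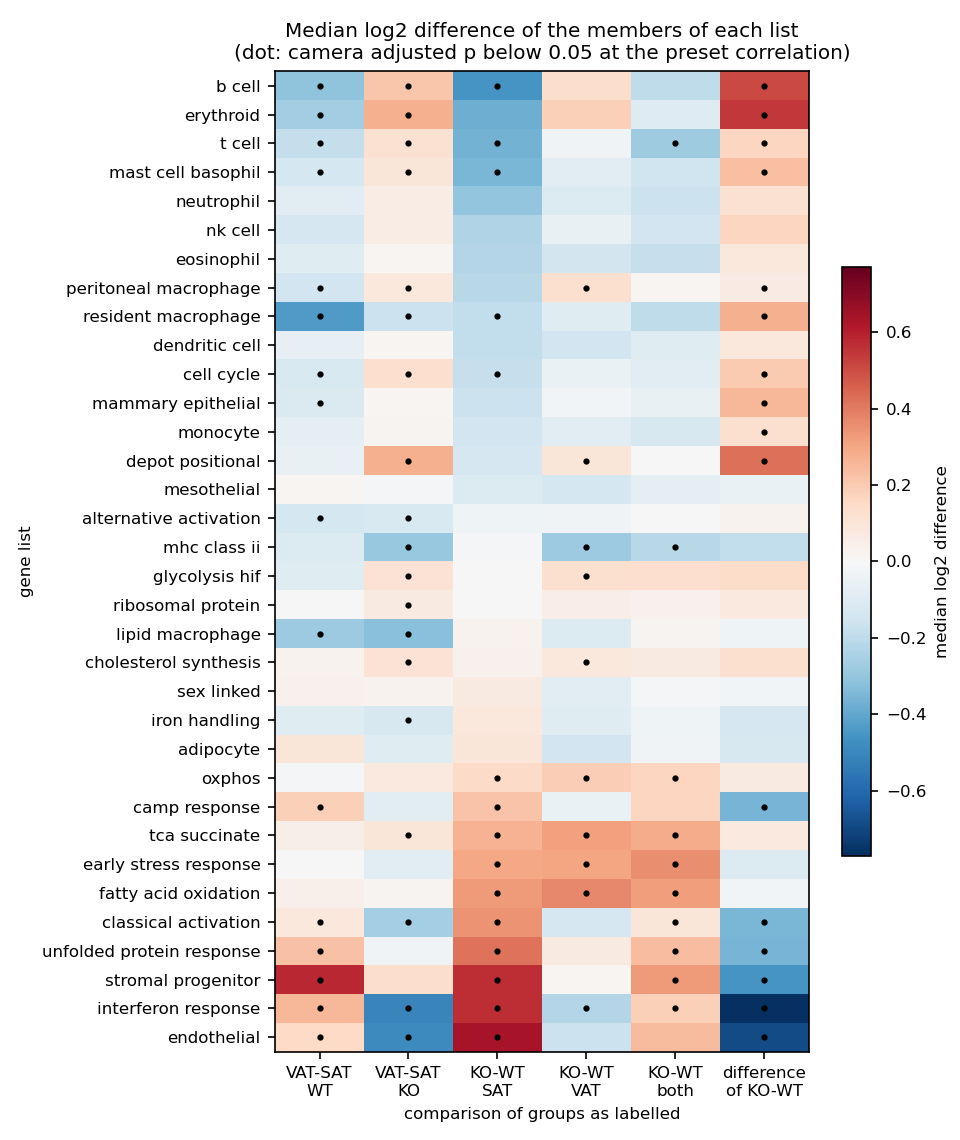
Median log2 change of each gene list in the 6 comparisons, by colour (red higher, blue lower), with a dot where the list passed the test at the preset correlation; with an estimated correlation 1 of these calls held. Interferon response genes had a median of 0.57 in KO SAT against WT SAT and -0.23 in KO VAT against WT VAT.

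The difference between the knockout effects, that in VAT minus that in SAT, tests whether the knockout acts differently in the depots as labelled. If depot labels were exchanged in 1 genotype, which is left open below, it would not test this. The difference was 8.72 ± 0.21 for Akr1c18 (SE, n = 4 pools per group, adjusted p = 1.58e-12), 6.36 for Adh7, 6.29 for Tnnc2, 4.59 for Emx2 and -6.71 ± 0.74 for Svs4 (adjusted p = 4.96e-05). Effects on chemokine genes differed in both directions, with Ccl8 at 5.06 ± 0.28 (adjusted p = 2.24e-08), Cxcl10 at -3.11, Ccl5 at -3.21 and Ccl2 at -1.45. Fcna and Folr2 were at 2.99 and 1.77.

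Interferon response genes had lower effects in VAT (10 of 21, 20 adjusted over the list alone), with Parp14 at -1.08 and Ifit3 at -0.78. The interferon median was -0.77 (adjusted p = 4.58e-21, and adjusted p = 0.0969 with an estimated correlation). So did classical activation genes, 9 of 34 with 1 higher (15 and 2 adjusted over the list alone), with Saa3 at 3.31 as the exception. The classical activation median was -0.35 (adjusted p = 8.64e-08, and adjusted p = 0.0969 with an estimated correlation). B cell markers had higher effects in VAT (6 of 16, 9 adjusted over the list alone), with Cd79a at 1.73 and Cd79b at 1.59. The B cell median was 0.51 (adjusted p = 9.52e-08, and adjusted p = 0.0969 with an estimated correlation). T cell markers did too (6 of 17, 7 adjusted over the list alone), with Icos at 3.05 and Cd3e at 2.54. The T cell median was 0.16 (adjusted p = 4.18e-07, and adjusted p = 0.0969 with an estimated correlation). Peritoneal macrophage genes had higher effects in VAT (6 of 19 higher and 2 lower, the same adjusted over the list alone), with Prg4 at 3.41, Cxcl13 at 2.88 and Slpi at 2.60. The peritoneal median was 0.07 (adjusted p = 0.0053, and adjusted p = 0.0969 with an estimated correlation). Positional genes did as well (8 of 20 higher and 3 lower, 10 and 4 adjusted over the list alone). The positional median was 0.42 (adjusted p = 0.00607, and adjusted p = 0.0969 with an estimated correlation). Cell cycle genes had higher effects too (2 of 24, 5 adjusted over the list alone, median 0.20, adjusted p = 0.00103, and adjusted p = 0.0969 with an estimated correlation). Endothelial markers had lower effects in VAT (5 of 20, 8 adjusted over the list alone). The endothelial median was -0.69 (adjusted p = 2.27e-09, and adjusted p = 0.148 with an estimated correlation). Stromal markers had lower effects too (5 of 20 lower and 1 higher, 11 and 2 adjusted over the list alone). The stromal median was -0.45 (adjusted p = 9.51e-05, and adjusted p = 0.261 with an estimated correlation). The alternative activation list did not differ (1 of 29 higher and 3 lower, the same adjusted over the list alone), although its members Ccl24 (-2.45), Tgm2 (-1.05) and Egr2 (-0.92) did. The alternative activation median was 0.03, mean -0.06 (adjusted p = 0.664). Resident macrophage genes had higher effects in VAT (4 of 26 higher and 2 lower, the same adjusted over the list alone, median 0.27, adjusted p = 0.0053, and adjusted p = 0.551 with an estimated correlation). So did markers of monocytes (4 of 15 and 1 lower, 5 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.0357, and adjusted p = 0.114 with an estimated correlation). Effects were higher for mast cell and basophil markers (2 of 13 and 1 lower, 4 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.00103, and adjusted p = 0.261 with an estimated correlation). They were higher for mammary epithelium (4 of 16, 4 and 1 lower adjusted over the list alone, median 0.25, adjusted p = 0.0109, and adjusted p = 0.317 with an estimated correlation) and for erythroid cells (3 of 7, 4 adjusted over the list alone, median 0.55, adjusted p = 0.000389, and adjusted p = 0.159 with an estimated correlation). Effects were lower in VAT for the unfolded protein response (2 of 20 and 1 higher, 4 and 1 adjusted over the list alone, median -0.36, adjusted p = 0.000907, and adjusted p = 0.551 with an estimated correlation). They were lower for cyclic AMP response (1 of 16, 1 adjusted over the list alone, median -0.36, adjusted p = 0.00949, and adjusted p = 0.25 with an estimated correlation).

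The knockout effect differed between depots for 722 genes, 359 higher and 363 lower in VAT, of which 377 differed at least 2-fold. On day 1 alone 330 genes passed and on day 2 alone 1904 (736 higher and 1168 lower), against 1694 with array spread as a term (1085 higher and 609 lower) and 1310 without WT VAT pool 1. Of the 16 lists that passed, 11 kept the call with array spread as a term. The 5 that lost it were monocytes (median 0.066), mast cells and basophils (0.090), mammary epithelium (0.16), the unfolded protein response (-0.11) and cyclic AMP response (-0.19). Medians of 2 others moved by over 1.5 times with that term, to 0.092 for the cell cycle and -0.029 for peritoneal macrophages. The lists of dendritic cells, neutrophils, eosinophils, NK cells, adipocytes, mesothelium and sex-linked genes, 7 in all, passed in none of the 6 comparisons; the smallest adjusted p was 0.0716, for 10 eosinophil markers in KO SAT against WT SAT (median -0.22).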

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

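The tests of exchanged labels, of a turned-round depot effect, of carried-over tissue, of array spread, of splits within a day and of permuted residuals were chosen after the results they bear on had been seen; the receptor gene test and the counts over the other splits were set before.

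Most depot differences that passed on the arrays labelled KO and on those labelled WT ran against each other: of 123 genes that passed in both genotypes, 100 went in opposite directions and 23 in the same, as did 3 of 12 lists that passed in both (in wild type and knockout, lipid-associated at -0.28 and -0.32, resident macrophage at -0.44 and -0.16, alternative activation at -0.13 and -0.11), and over all 17097 genes the Spearman correlation was 0.0085. An effect of Sucnr1 loss on macrophages is assumed, untested, to spare genes that mark fat by body position. Over the 20 positional genes the depot effects of the genotypes had a Spearman correlation of -0.768 (bootstrap 95% interval -0.953 to -0.441, permutation p = 0.00015). Neither counts variation between pools. Tissue carried over into KO SAT alone would leave KO VAT and WT VAT alike at the genes that turned. Of these 100, 75 passed between KO VAT and WT VAT in the direction of the turn, where 15.9% of all genes passed in either direction. The 100 were chosen with values of both groups, which favours such passes, so this test does not settle whether carry-over took part. Exchanged depot labels within 1 genotype may account for the opposite directions. On a score of 60 genes chosen on the wild-type arrays alone, 8 of 8 knockout arrays lay on the side opposite to their label, KO SAT at 1.80 ± 0.26 and KO VAT at -0.15 ± 0.10 (SD, n = 4). Against an exchange alone stand the genes and lists that kept their direction, and KO VAT only just past the midpoint and far from WT SAT at -1.63 ± 0.11. Counts of genes between groups decide nothing here, since both knockout groups differed at more genes from WT SAT (KO SAT 6279, KO VAT 6717) than from WT VAT (1178 and 2724). An exchange is a hypothesis that would leave the averaged knockout effect as it is. The knockout effects within a depot, and their difference, would then set SAT of 1 genotype against VAT of the other. An untested change in the tissue around the macrophages stays open beside it, as do an effect of Sucnr1 loss and carry-over into KO SAT. Which genotype's labels an exchange would concern is open too. Svs4 at 11.44 in KO SAT and muscle Tnnc2 at 9.80 in WT SAT against 5.64 in WT VAT would place it in the knockout labels. Svs4 at 7.30 in WT SAT pool 2 and peritoneal macrophage genes, with a median VAT minus SAT of 0.08 in knockout and -0.15 in wild type, would place it in the wild-type labels.

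The knockout count over both depots, 8831, went with array spread. Narrower values on the wild-type arrays could account for part of it. Across 17097 genes the slope on array spread within groups correlated with the knockout effect at r = 0.792. In 100 shuffles within groups r reached 0.772. Genomic DNA carried over into the wild-type arrays could do so as well, since 78 olfactory and vomeronasal receptor genes had a median knockout effect of -0.24, at percentile 0 of 10000 random lists of like mean (95% of them between -0.14 and -0.07), with 50 lower and 1 higher. With array spread as a term that median was -0.01, at percentile 15.4, so these tests do not separate DNA from other causes of a narrower spread. An effect of Sucnr1 loss on many genes stays open beside both. Spread differed by genotype, so the spread term can remove such an effect too and does not weigh against it. With that term 483 of the 8831 genes passed, 467 with the same sign.

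Splitting the arrays in other ways tests whether arbitrary grouping can give such counts. For KO SAT against WT SAT (6279 genes), KO VAT against WT VAT (2724) and KO VAT against KO SAT (738), 1 of 35 splits, the real one, gave as many, and the highest of the other splits gave 0, so chance is an unlikely source if arrays are exchanged across days. Of the 35 splits, 18 keep 2 pools of each day on each side; these are too few for a share under 0.05, and the highest of the others among them was 0 as well. Over both depots, 1 of 100 splits reached 8831 (highest other 1668), as did 1 of 100 drawn within depot and day (highest other 5881). Chance is an unlikely source of the whole count, though arbitrary labels gave as many as 5881 genes. Splits of this kind mix the genotypes, so the 1 of 100 that reached 722 for the difference of the knockout effects (highest other 545) decides nothing about that difference. With the effects of genotype, depot and day kept and the residuals permuted within a day, 2 of 100 arrangements, the real one included, reached 722 (highest other 814). Chance is thus unlikely to give that count but is not excluded, since 1 arrangement gave more genes than the real one.

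In the wild-type depot comparison 4 of 35 splits gave at least 486 genes, with 3998 as the highest other, so chance cannot be excluded. The 3 splits with more genes than depot, at 3998, 3815 and 2757, point to a structure among the 8 wild-type arrays other than depot. That structure may be array spread: 2 of these splits set 3 of the 4 arrays of smallest spread together and the split with 2757 all 4, and with array spread as a term they gave at most 1 gene. With that term depot gave 1502 genes and the highest other split 553. Whether a difference in spread alone gives such counts is not settled. Of the 6 splits with as large a difference, 3 gave 0 genes without the term. Those 3 did not balance the days, a fixed term, over their sides, and neither did the split with 2757.

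On 25 of 556 groups tested, 1 array lay far from the other 3; chance gives about 1 in 20, or 27.8, so these are no more than chance would give. The share of the range taken by the gap was 0.915 for the array median of KO VAT, where pool 2 stood apart. In WT SAT, pool 2 stood apart for Ceacam10 (0.928), Svs2 (0.890), Svs4 (0.925) and H2-Ob (0.887), pool 1 for Fcna (0.984), pool 3 for Ifih1 (0.887), and pool 4 for Mfap5 (0.865) and Thbs2 (0.838). In WT VAT, pool 3 stood apart for H2-DMb1 (0.835), pool 4 for Sprr2a1 (0.851) and pool 1 for Svs4 (0.832). In KO SAT, pool 1 stood apart for Cd36 (0.853), F13a1 (0.842) and Rsad2 (0.859), and pool 2 for Igkj1 (0.994), Serpinb2 (0.871), Ssty1 (0.908) and Tgm2 (0.890). Pool 3 of KO SAT stood apart for Fcgr4 (0.891) and Slpi (0.982), and pool 4 for Rdh10 (0.904). In KO VAT, pool 1 stood apart for Hbb-b2 (0.8293) and pool 2 for Mfap5 (0.892) and Ppard (0.911).

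The knockout effect in VAT minus that in SAT passed limma's test for 85 of 135 named genes, 44 higher and 41 lower (log2 units, n = 4 pools per group). Genes of tissue enzymes, muscle, matrix and position that were higher were Akr1c18 (8.72), Adh7 (6.36), Tnnc2 (6.29), Atp2a1 (5.99), Thbs2 (5.51), Acta1 (5.19), Emx2 (4.59), Prkg2 (4.05), Sfrp2 (3.33), Idi1 (3.08), Dsp (2.97), Hoxc10 (2.12), Krt14 (1.54) and Thy1 (1.32). Genes of macrophages and secreted factors that were higher were Ccl8 (5.06), Serpinb2 (4.50), Prg4 (3.41), Saa3 (3.31), Fcna (2.99), Cxcl13 (2.88), Slpi (2.60), F13a1 (1.77), Folr2 (1.77), S100a4 (1.73), Ctsk (1.26), Fcgr4 (1.24), Ctsl (0.70) and Gpnmb (0.62). Lymphocyte, red cell and MHC genes that were higher were Igkj1 (5.38), Hbb-b2 (4.37), Icos (3.05), Cd3e (2.54), Cd3g (1.80), Cd79a (1.73), Cd79b (1.59), Blk (1.46), Cd3d (1.42), H2-Ob (1.27), H2-DMb2 (0.85) and Lat (0.83). Regulators that were higher were Egln3 (2.04), Adm (1.496), Jun (1.23) and Ppard (0.95), which did not pass without WT SAT pool 1 or 3, KO SAT pool 1, 2 or 3, or KO VAT pool 1, 3 or 4 (0.88 to 0.96).

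Seminal vesicle and related genes with lower effects in VAT were Svs4 (-6.71), Svs6 (-6.02), Svs3a (-5.95), Svs2 (-5.91), Ceacam10 (-4.69) and Pate4 (-3.88). Matrix, vessel, transport and position genes that were lower were Tnfrsf11b (-5.36), Slc7a2 (-5.26), Cxcl12 (-4.33), Ltbp4 (-4.24), Rdh10 (-3.76), Cdh5 (-2.83), Mfap5 (-2.21), Fstl1 (-1.17), Tek (-1.12) and Hoxc8 (-0.95). Chemokine, cytokine and macrophage genes that were lower were Ccl5 (-3.21), Cxcl10 (-3.11), Il6 (-2.97), Ccl24 (-2.45), Fabp4 (-1.49), Ccl2 (-1.45), Itgax (-1.44), Cd86 (-1.44), Tgm2 (-1.05), Cxcl1 (-0.98), Egr2 (-0.92) and Igf1 (-0.83). Interferon, MHC and stress genes that were lower were Cmpk2 (-1.40), H2-Eb1 (-1.34), Trib3 (-1.33), Ifit1 (-1.09), Parp14 (-1.08), Hspa1b (-1.05), Mx1 (-0.97), Cd74 (-0.96), H2-Ab1 (-0.80), Irf1 (-0.79), Ifit3 (-0.78), Rsad2 (-0.74) and Calr (-0.73).

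Camera at the preset correlation passed 16 gene lists for the same difference, and 0 with an estimated correlation (adjusted p of 0.0969 to 0.551). Median differences of the knockout effects were -0.77 for interferon response, -0.69 for endothelial, -0.45 for stromal and -0.35 for classical activation genes. They were -0.36 for unfolded protein and cyclic AMP responses. They were 0.51 for B cell, 0.16 for T cell, 0.55 for erythroid, 0.23 for mast cell and basophil, 0.27 for resident macrophage and 0.065 for peritoneal macrophage markers. They were 0.20 for cell cycle, 0.42 for positional, 0.25 for mammary epithelial and 0.13 for monocyte genes.

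Among the 15588 probe sets that the probe table at hand does not list, 5365 passed between KO SAT and WT SAT and 1717 between KO VAT and WT VAT. Over both depots 7479 passed, and for the difference of the knockout effects 343. Between depots 178 passed in wild type and 393 in knockout. Their genes were not analysed here.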

How the results depend on the processing

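The spread term and the fit without the 4 arrays of smallest spread were chosen after seeing the data. Counts stayed within 1.5 times the reported one under 12 of 16 alternatives in KO SAT against WT SAT, 10 of 16 in KO VAT against WT VAT, 12 of 15 over both depots, 9 of 16 for the difference of the knockout effects, 7 of 17 in the wild-type depots and 8 of 17 in the knockout depots. Of 4387 named gene values under alternatives, 4060 kept direction and side of the threshold, 288 lost and 21 gained the call and 18 changed sign. With the spread term 64 of 272 values lost the call. With arrays left out, 25 of 256 named gene calls were lost at least once. Unless stated, the cause was not tested, and single days hold fewer arrays. Genes near background, such as Sucnr1, are limited by signal.

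In the order KO SAT against WT SAT, KO VAT against WT VAT, difference of the effects, wild-type depots and knockout depots, counts were 3563, 986, 455, 212 and 422 with no day term, 582, 5376, 330, 199 and 262 on day 1, and 9820, 7359, 1968, 2340 and 1964 with the residual component as a term. On day 2, KO VAT against WT VAT gave 331, both depots 4279, the difference 1904 and the depots 4222 and 199. With array spread as a term, KO SAT against WT SAT gave 1308, both depots 1353, the difference 1694 and the depots 1502 and 1968. Without the 4 arrays of smallest spread, KO VAT against WT VAT gave 1503, both depots 4670, the difference 1834 and the depots 2129 and 1685. From the compared arrays alone, KO VAT against WT VAT gave 1238 and the depots 60 and 2047. Quantile normalization gave 1148 and 1110 in the depots and centring 315 in wild type; array weights gave 1209 for the difference and 2203 in the knockout depots. With the pool number as a replicate block, KO SAT against WT SAT gave 5579, and a fixed block within genotype gave 222 in the wild-type depots. The pool numbers did not pair the arrays: 5 of 24 same-number pairs correlated above 0.1.

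With each array left out, counts ran from 3071 (without WT SAT pool 4; 3625 without KO SAT pool 1) to 7960 in KO SAT against WT SAT. They ran from 1115 (without KO VAT pool 1; 1541 and 1507 without WT VAT pools 1 and 2, 1467 and 1302 without KO VAT pools 2 and 3) to 4007 in KO VAT against WT VAT. They ran from 7289 to 9469 over both depots and from 546 to 1310 (without WT VAT pool 1) for the difference. In the wild-type depots they ran from 231 (without WT VAT pool 3; 249 without WT SAT pool 3) to 1711 (without WT VAT pool 1), and in the knockout depots from 461 (without KO SAT pool 2; 468 without KO SAT pool 3) to 1054.

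Of 86 list calls, 50 held with array spread as a term, 26 were lost and 10 turned, and 19 were lost without the 4 arrays of smallest spread. Lists that passed numbered 0, 0, 0, 0, 0 and 1 (knockout depots) with an estimated correlation, 6 in KO VAT against WT VAT and 5 over both depots without dim probe sets, and 10 in the wild-type depots without the 4 arrays. With array spread as a term, lists turned downward in KO SAT against WT SAT (citric acid cycle adjusted p = 0.0522, oxidative phosphorylation 3.56e-07, fatty acid oxidation 0.649, unfolded protein response 0.263), in KO VAT against WT VAT (hypoxia and glycolysis 0.892, oxidative phosphorylation 0.414) and over both depots (interferon 0.112, citric acid cycle 0.565, oxidative phosphorylation 0.000205, unfolded protein response 0.0128).

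No sign change of a named gene concerned one that had passed. Among all genes some did with the spread term, as given above. Sucnr1 in KO SAT was -0.042 on day 2 and -0.017 to 0.024 with arrays left out, and in KO VAT -0.021 on day 1 and -0.030 to 0.035. In the wild-type depots Sucnr1 was 0.046 on day 1 and -0.048 to 0.015 with arrays left out, in the knockout depots -0.043 to 0.0038 and over both depots -0.013 to 0.020. For the difference Sucnr1 was -0.071 on day 1, -0.011 centred, -0.015 after quantile normalization, -0.014 with the spread term and -0.034 to 0.031 with arrays left out; Lyz2 was -0.21 on day 1 and -0.059 to 0.16. In KO SAT, Retnla was -0.012 on day 2, -0.30 after quantile normalization, -0.023 with array weights and -0.087 to 0.12 with arrays left out, and Mrc1 0.070 on day 2 and -0.32 to 0.020. In KO VAT, Arg1 was -0.072 on day 2, -0.18 after quantile normalization, -0.22 with the spread term, -0.18 without the 4 arrays and -0.076 to 0.38 with arrays left out, Retnla -0.022 after quantile normalization, Chil3 0.024 centred and 0.012 after quantile normalization, and Il6 0.42 on day 1 and -0.49 to 0.11 with arrays left out.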

Other observations

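Comparisons across depots were chosen after the depot results had been seen, and give values under the exchange of depot labels weighed above. KO SAT minus WT VAT, as labelled, passed for 1178 genes, 806 higher and 372 lower. KO VAT minus WT SAT passed for 6717 genes, 3131 higher and 3586 lower. Such counts decide nothing about an exchange. The crossed comparisons were not run with array spread as a term. The groups keep their labels in every other comparison.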
